A study of Mus musculus with 6 samples.

How the data were processed

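The study used RAW264.7 cells, a mouse macrophage-like line. Per the labels, all 6 samples received lipopolysaccharide (LPS, bacterial endotoxin) at 100 ng/mL for 48 h, and 3 of them were also exposed to low-intensity pulsed ultrasound (LIPUS) at 45 mW/cm2 for 25 min in each of 2 sessions 24 h apart. Per the labels' protocols, mRNA was selected by its poly(A) tail and fragmented, libraries were built with an NEBNext Ultra kit and sequenced as paired-end Illumina reads. The submitters' processing notes name bcl2fastq and the mouse build mm10. The aligner, the counting tool and the annotation release are not given in the sources used here, and neither is whether reads were counted by strand.

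The authors deposited a table of raw read counts per gene with the gene length, a table of raw read counts per transcript, and tables of their own comparison. The deposited gene table also holds TPM, which per the file headers and the values is the count divided by the length and scaled to the same total in every library. In the transcript table a read can count for several transcripts, so its totals were 3.32 to 3.49 times those of the gene table. The authors' deposited comparison tables give a log2 fold change (LPS with LIPUS over LPS), an unadjusted p-value and, per library, a normalised count, a signal close to the raw count times one factor per library. The test behind these columns is not stated in the files. edgeR's exact test with TMM scaling and tagwise dispersion on all 39089 genes gave the same p-values as the authors' deposited table within 5.16e-10, and its pseudo-counts matched the deposited normalised counts within 1.37e-08.

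Everything else was computed from the deposited counts in R 4.3.3. Samples were grouped by their labels into LPS (n = 3) and LPS with LIPUS (n = 3). The main test was edgeR 4.0.16's quasi-likelihood test (glmQLFit and glmQLFTest) with TMM scaling, group as the one term, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Genes passed the filter of filterByExpr (minimum count 10, by group), which kept 12571 of 39089 genes and 99.9% of the counts. It removed 8209 genes with counts, and 18309 had no count in any library. Standard errors and 95% intervals come from the same fit. Fold changes are LPS with LIPUS over LPS. For genes removed by the filter, summed counts are compared and the 95% interval of their ratio is exact and covers counting error only. A count of 0 allows up to 3 counts, which was 0.188 to 0.212 CPM per library. All other CPM values are counts relative to the TMM-scaled library size.

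The design, the gene lists, the rule for named genes and most alternatives were set before the data were examined. The 34 gene lists cover macrophage activation, Wnt signalling, pathways that respond to a mechanical stimulus, metabolism, cell growth, RNA quality and markers of other cell types. Each list was tested with camera in limma 3.58.1 (preset correlation 0.01, against all other genes), adjusted over the 32 lists with a tested member, and again with an estimated correlation and with fry. Camera asks whether a list moved relative to other genes, and fry whether its genes move, on balance, one way. The count of list members past the threshold is given over all genes tested and adjusted over the list alone. The genes named are those in the series title (Wnt2b, Axin1, Axin2 and Ctnnb1), a fixed set of 7 activation genes, up to 4 members with the smallest p in each list, and, since no gene passed the threshold, the 5 genes with the smallest p in each direction among those with a mean of at least 2 CPM, no overlap between groups and a gene name that is not a clone or predicted name. Genes outside that rule are said to be so where they appear.

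Alternatives were DESeq2 1.42.0 with its own size factors, DESeq2 size factors and upper-quartile scaling in edgeR, limma-voom, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), no filter, a filter of 1 CPM in 3 libraries, stricter thresholds, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were per-library trends of gene length and GC content removed as offsets, and edgeR's exact test with and without adjustment. GC content came from GENCODE M21 transcripts on the same assembly, matched by symbol for 93.5% of the tested genes. Coordinates are the deposited ones, and their starts and ends are 1-based.

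Total counts were 14171061 to 15956693 per library. The biological coefficient of variation was 5.84%, and the median standard error of a gene's log2 fold change was 0.09. The main test was tested on simulated data for this comparison: counts were drawn for the real genes with 200 of them changed by known folds, and 12537 genes passed the filter. It recovered 46.3% of 67 genes changed 1.25-fold, 76.1% of 67 changed 1.5-fold and 81.8% of 66 changed 2-fold, with 8 false calls. These shares hold for 200 changed genes, each drawn independently. With fewer changed genes the adjustment is stricter, and differences that many genes of a library share were not simulated, so recovery in the real data can be lower. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom was 2.54 to 9.17 within groups and 3.00 to 6.73 between them. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which can be technical. The study's cells without LPS, if any, were not analysed here. Mitochondrially encoded genes were not analysed here either.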

Results

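RNA was measured in 6 poly(A)-selected libraries of LPS-treated RAW264.7 cells, 3 without ultrasound and 3 with it. The gene table held 15956693, 15606264 and 14984236 counts in LPS libraries 1 to 3 and 14534963, 14632288 and 14171061 in LIPUS libraries 1 to 3, so the LPS libraries were slightly deeper. Each library had counts for 16996 to 17168 genes. Across genes, Spearman correlations of log2 CPM were 0.994 to 0.996 for every pair of libraries, with a median of 0.996 within groups and 0.996 between them. The first 2 principal components held 25.2% and 21.95% of the variance. The first did not separate the groups. On the second the LPS libraries lay at -15.6 to -1.02 and the LIPUS libraries at 0.43 to 16.6. Chance gives such a separation in 10% of arrangements on 1 component chosen in advance, and more often when 2 are examined.

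The comparison of LPS with LIPUS against LPS alone addresses whether transcript levels of LPS-treated cells differ with ultrasound. All libraries analysed had LPS, so the response to LPS itself was not measured. Transcript levels in the 2 groups were close: the median absolute log2 fold change over 12571 genes was 0.07, and no gene passed the test. The genes with the smallest p among the higher ones were Thoc2, a subunit of the complex that exports mRNA from the nucleus, Socs4, of the family that restrains cytokine signalling, Mki67, the proliferation marker Ki-67, Smc5, of the SMC5/6 complex of DNA repair, and Rev3l, the catalytic subunit of DNA polymerase zeta. Thoc2 had 89.7 ± 2.51 CPM with LPS and 112.9 ± 10.9 CPM with LIPUS (SD, n = 3 each), a log2 fold change of 0.33 ± 0.06 (SE, adjusted p = 0.241). Socs4 had a log2 fold change of 0.32 ± 0.06 (adjusted p = 0.243), Mki67 0.25 ± 0.05 (adjusted p = 0.284), Smc5 0.26 ± 0.06 (adjusted p = 0.354) and Rev3l 0.43 ± 0.10 (adjusted p = 0.354).

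Among the lower genes, the smallest p belonged to Rn7s2, a copy of 7SL RNA, the RNA of the signal recognition particle. Its counts were 114, 2601 and 1047 in the LPS libraries and 104, 63 and 56 in the LIPUS libraries, a log2 fold change of -3.98 ± 0.68 (SE, adjusted p = 0.197, the smallest of all genes). The near-identical copy Rn7s1, with which it can share reads, had 110, 904 and 521 counts against 113, 88 and 48 (-2.53 ± 0.47, adjusted p = 0.241). For both, LPS library 1 was at the level of the LIPUS libraries. Leaving out 1 library at a time gave -4.52 to -2.91 for Rn7s2 (adjusted p = 5.94e-07 to 0.667). For Rn7s1 it gave -3.01 to -1.86 (adjusted p = 2.24e-06 to 0.713). The next 4 were B3galnt1 and Ggta1, which encode enzymes that add sugars to glycolipids and glycoproteins, Chst14, whose enzyme sulfates dermatan sulfate, and Pdzd7, which encodes a PDZ-domain scaffold protein. B3galnt1 had 4.70 ± 0.36 CPM with LPS and 2.88 ± 0.50 with LIPUS (SD, n = 3 each), a log2 fold change of -0.71 ± 0.20 (adjusted p = 0.699). The log2 fold changes of Ggta1, Chst14 and Pdzd7 were -0.23 ± 0.07, -0.51 ± 0.15 and -0.50 ± 0.16 (adjusted p = 0.714 to 0.794).

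By edgeR's quasi-likelihood test 0 of 12571 genes passed an adjusted p of 0.05, and 579 had an unadjusted p below 0.05 (376 higher, 203 lower) where 628.6 are expected with no difference. DESeq2 and limma-voom also called 0. In 1222 genes (9.72%) the groups did not overlap, and chance gives 10%. The 95% interval of the fold change lay within 1.25-fold for 59.6% of tested genes, within 1.5-fold for 80.1% and within 2-fold for 92.7%. The count moved with single libraries: it was 2 without LPS library 1 (Rn7s1 and Rn7s2), 3 without LIPUS library 2 (Thoc2, Atrx and Gm10499) and 6 without LIPUS library 3 (Hspa1b, Fos, Fosb, Socs4, H2af-ps2 and Ccnl1), with Atrx, Gm10499, H2af-ps2 and Ccnl1 named here after their values were seen. It was 5 with the replicate number as a block (Gm10499, Rn7s2, Fos, Fosb and Rn7s1), 31 with no filter on low counts and 7 by edgeR's exact test on all genes.

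**Figure D1:**
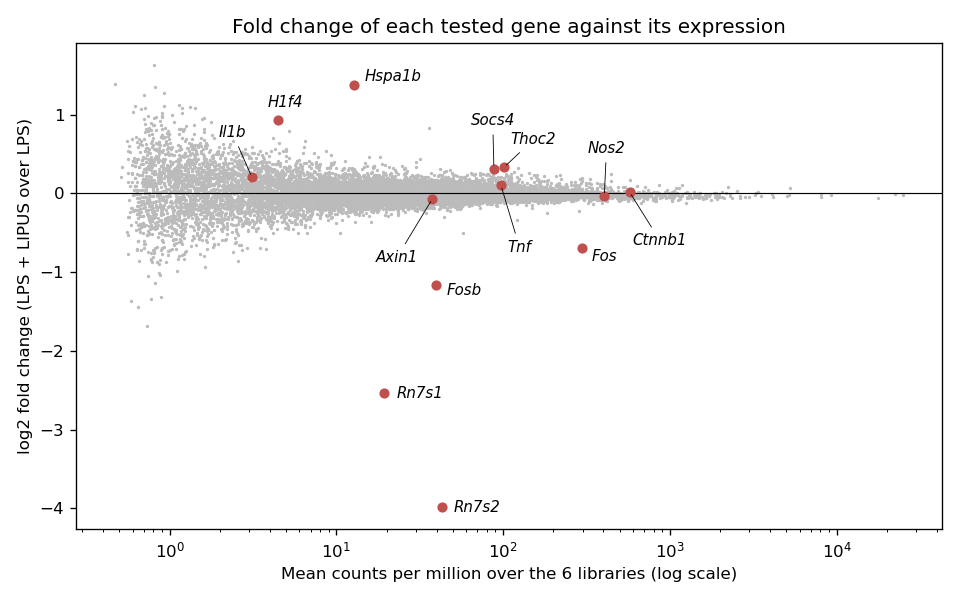
Each grey point is 1 of the 12571 tested genes; the x axis is the mean of the 2 group means in CPM on a log scale, and the y axis is the log2 fold change of LPS with LIPUS over LPS. Some of the genes named in the text are red and labelled. Among these, Rn7s2 (-3.98) and Rn7s1 (-2.53) lie farthest from 0, while Nos2, Tnf, Axin1 and Ctnnb1 lie within the band of the other genes.

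The study asks whether ultrasound lowers the pro-inflammatory (M1) state that LPS induces, so M1 genes were compared as a group. Nos2, the inducible nitric oxide synthase, had 409.4 ± 8.98 CPM with LPS and 399.5 ± 5.96 CPM with LIPUS (SD, n = 3 each). Its log2 fold change was -0.04 ± 0.05 (SE, 95% interval -0.14 to 0.07, adjusted p = 0.999). Tnf, the tumour necrosis factor gene, had 93.4 ± 4.33 CPM against 100.6 ± 1.13 CPM, a log2 fold change of 0.11 ± 0.05 (interval -0.01 to 0.22, adjusted p = 0.999). Il1b, which encodes interleukin-1 beta, was low at 2.89 ± 0.77 CPM and 3.34 ± 0.44 CPM (0.21 ± 0.23, adjusted p = 0.999), and Il6 had 7 counts in the LPS libraries together and 4 in the LIPUS libraries.

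Of the 32 M1 genes listed, 22 could be tested; 12 had a positive and 10 a negative fold change, 0 passed over all genes and 0 when adjusted over the list alone. The members with the smallest p were Socs3 (log2 fold change -0.19 ± 0.09), an inhibitor of cytokine signalling, Tnf, the chemokine gene Ccl2 (-0.25 ± 0.13) and the prostaglandin synthase gene Ptgs2 (0.11 ± 0.06). The list's median log2 fold change was 0.01 and its mean 0.00 (95% interval over its genes -0.06 to 0.06), and camera gave an adjusted p of 0.934. For 12 of the 22 genes the interval of the fold change lay within 1.25-fold and for 17 within 1.5-fold. The median was -0.05 without LIPUS library 2 and 0.07 without LIPUS library 3, neither past the test.

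Several genes of the alternative (M2) state were at low counts. Arg1, the arginase gene, had 10 counts over the LPS libraries and 4 over the LIPUS libraries, Mrc1, the mannose receptor gene, 12 and 10, and Il10, the interleukin-10 gene, 10 and 16, all below the filter of the main test. Of the 31 M2 genes listed, 17 were tested, 10 with a positive and 7 with a negative fold change, and 0 passed over all genes or adjusted over the list alone. Cd36, a scavenger receptor gene, had a log2 fold change of 0.16 ± 0.10, Klf4 -0.19 ± 0.13, Egr2 0.27 ± 0.20 and Irf4 0.45 ± 0.37. The list's median was 0.05 and camera gave an adjusted p of 0.667.

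**Figure D2:**
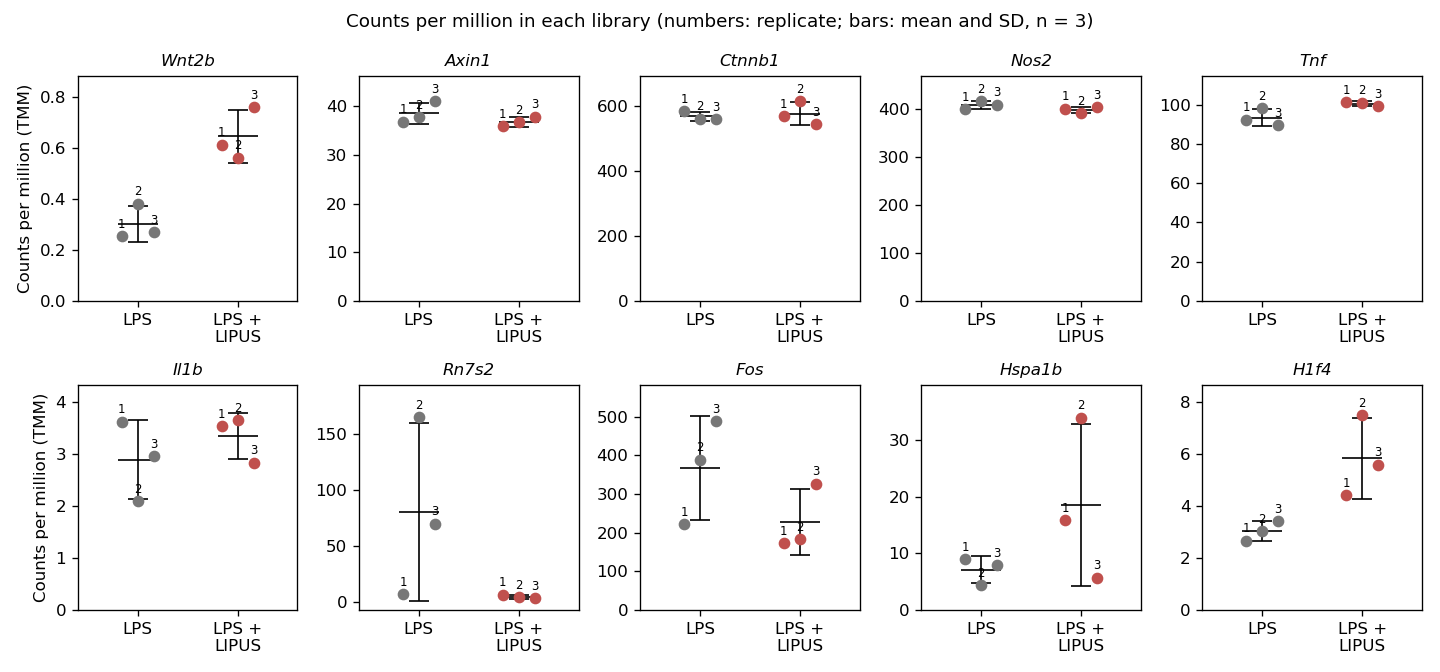
CPM (TMM-scaled, linear y axes) of 10 genes in each library, grey for LPS and red for LPS with LIPUS; numbers give the replicate and black bars the mean and SD of 3 libraries. Wnt2b separates the groups at 0.30 and 0.64 CPM, Nos2 and Ctnnb1 do not, and in Rn7s2, Fos and Hspa1b the libraries of 1 group differ by more than the groups do.

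The series title names Wnt2b, AXIN and beta-catenin, members of the Wnt pathway. Wnt2b, which encodes a Wnt ligand (mm10, chromosome 3, 104944805 to 104961709, minus strand), had 4, 6 and 4 counts in the LPS libraries and 9, 8 and 11 in the LIPUS libraries. That is 14 against 28 counts, or 0.30 ± 0.07 against 0.64 ± 0.10 CPM (SD, n = 3 each), a ratio of 2.15 with a 95% counting interval of 1.09 to 4.42. Axin1 (chromosome 17, 26131217 to 26195811, plus strand), which encodes a scaffold of the complex that degrades beta-catenin, had 38.6 ± 2.19 CPM against 36.9 ± 1.01 CPM, a log2 fold change of -0.06 ± 0.07 (SE, 95% interval -0.22 to 0.09, adjusted p = 0.999). Axin2 (chromosome 11, 108917828 to 108950783, plus strand), a gene that beta-catenin signalling commonly induces, had 1 count in all 6 libraries. Ctnnb1 (chromosome 9, 120933400 to 120960507, plus strand), which encodes beta-catenin, had 569.0 ± 14.1 CPM against 576.8 ± 35.8 CPM (log2 fold change 0.02 ± 0.06, 95% interval -0.10 to 0.14, adjusted p = 0.999).

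Wnt2b was below the filter on low counts, so the main test gives it no p. Without the filter, edgeR's quasi-likelihood test gave it a log2 fold change of 1.07 (adjusted p = 0.899), and DESeq2 1.10 (adjusted p = 0.998). The gene is one the study singled out, so its direction in these samples is not independent evidence.

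The wider Wnt list of 73 genes had 30 tested members, 15 with a positive and 15 with a negative fold change, and 0 passed over all genes or adjusted over the list alone. Apc, which encodes another part of the beta-catenin degradation complex, had a log2 fold change of 0.24 ± 0.07 (SE, adjusted p = 0.794), Notum, a Wnt deacylase gene, -0.28 ± 0.15, the receptor gene Fzd2 -0.64 ± 0.41 and the ubiquitin ligase gene Btrc -0.12 ± 0.08. The Wnt targets Myc (0.02 ± 0.07) and Ccnd1 (-0.04 ± 0.05) and the ligand gene Wnt6 (0.02 ± 0.10), named here after their values were seen, lay near 0. The list's median was 0.005, its mean -0.01 (95% interval -0.07 to 0.05), and camera, whose direction was up, gave an adjusted p of 0.934.

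Genes that sense and pass on the LPS signal were tested as further lists, and none moved past the test. In the Toll-like receptor list 21 of 24 tested genes had a negative fold change, among them Tlr6 (-0.37 ± 0.15), Tlr9 (-0.33 ± 0.20) and the adaptor gene Ticam1 (-0.12 ± 0.06). Its median was -0.04 and camera gave an adjusted p of 0.0848. The NF-kB list had a median of -0.02 and a mean of 0.01 (adjusted p = 0.866), with Rel, an NF-kB subunit gene, at 0.24 ± 0.07. Interferon-response genes had a median of 0.00 (adjusted p = 0.866) and inflammasome genes 0.08 (adjusted p = 0.482). In these 4 lists 0 genes passed over all genes or adjusted over the list alone.

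By camera with the preset correlation, 2 of the 32 tested lists passed. One was of replication-dependent histone genes, whose messages are made in S phase. Of 28 listed, 12 were found by name among the deposited genes and 8 were tested. In 7 of these 8 the fold change was positive, with a median log2 fold change of 0.68 and a camera adjusted p of 1.93e-05. The call did not hold with an estimated correlation (p = 0.0712, adjusted p = 0.608) or by fry (adjusted p = 0.784). The members were few and low, with H1f4 at 3.05 ± 0.38 CPM against 5.84 ± 1.55 CPM (SD, n = 3 each, log2 fold change 0.94 ± 0.21), H4c4 at 1.27 ± 0.47, H1f5 at 0.97 ± 0.41 and H2ac20 at 1.03 ± 0.47 on the log2 scale (SE). Leaving out 1 library at a time gave 0.72 to 1.11 for H1f4, 0.84 to 1.98 for H4c4, 0.69 to 1.26 for H1f5 and 0.36 to 1.37 for H2ac20. H1f4 was the one member past the threshold when adjusted over the list alone (adjusted p = 0.00262), and 0 passed over all genes. Histone genes are near-identical copies whose reads the authors' counting could split. Replication-dependent histone messages mostly lack a poly(A) tail, by which the libraries were selected, so their counts may not give message levels. Without LIPUS library 2 the list's median was 0.21 (camera adjusted p = 0.173). With the filter of 1 CPM in 3 libraries the median was 0.11 (camera adjusted p = 0.0401). Another 20 tested replication-dependent histone genes, outside the list and examined after the results were seen, had a median of 0.18, with 17 higher.

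The other list was of antioxidant genes under the transcription factor Nrf2: 24 of 29 tested members had a negative fold change, with a median log2 fold change of -0.06 and a camera adjusted p of 0.00739. This call did not hold either with an estimated correlation (p = 0.0950, adjusted p = 0.608) or by fry (adjusted p = 0.661). Hmox1, the haem oxygenase gene, had 1306 ± 61.5 CPM with LPS and 1197 ± 20.2 CPM with LIPUS (SD, n = 3 each), a log2 fold change of -0.13 ± 0.06 (SE). The next were Blvrb (biliverdin reductase, -0.12 ± 0.06), the peroxiredoxin gene Prdx1 (-0.10 ± 0.05) and the glutathione peroxidase gene Gpx4 (-0.09 ± 0.06). None passed over all genes or adjusted over the list alone, and for 27 of the 29 the interval lay within 1.25-fold. Camera's adjusted p was 0.241 without LPS library 3 and 0.0754 without LIPUS library 1.

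Immediate early and heat shock genes, which respond quickly to mechanical or thermal stimuli, held members that varied widely between libraries of the same group. Fos, an AP-1 transcription factor gene, had 3500, 6130 and 7272 counts in the LPS libraries and 2543, 2611 and 4729 in the LIPUS libraries, a log2 fold change of -0.69 ± 0.22 (SE, adjusted p = 0.794). Its relative Fosb had 274, 985 and 1267 against 158, 173 and 739 counts (-1.16 ± 0.46, adjusted p = 0.999), and Klf2 and Dusp1 were at -0.37 ± 0.13 and -0.33 ± 0.12. The heat shock gene Hspa1b had 140, 69 and 118 counts against 233, 484 and 82 (1.38 ± 0.39, adjusted p = 0.699). Without LIPUS library 3, Fos was at -1.04, Fosb at -2.26 and Hspa1b at 1.82, and these 3 passed the test (adjusted p = 0.0198, 0.0198 and 0.00188). With the replicate number as a block Fos and Fosb passed as well (adjusted p = 0.00465 and 0.0168). Leaving out a different library shrank all 3: without LPS library 3 Fos was at -0.42 and Fosb at -0.70 (adjusted p = 0.999 each), and without LIPUS library 2 Hspa1b was at 0.61 (adjusted p = 0.672). The immediate early list, with 33 tested, had a median of 0.01, a mean of -0.08 and a camera direction of down (adjusted p = 0.198), with 0 past the threshold adjusted over the list alone. The heat shock list, with 17 tested, had a median of 0.02 (adjusted p = 0.198), and Hspa1b passed when adjusted over the list alone (adjusted p = 0.0416). The list of mechanosensing and YAP genes had a median of -0.01 (24 tested, adjusted p = 0.866).

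**Figure D3:**
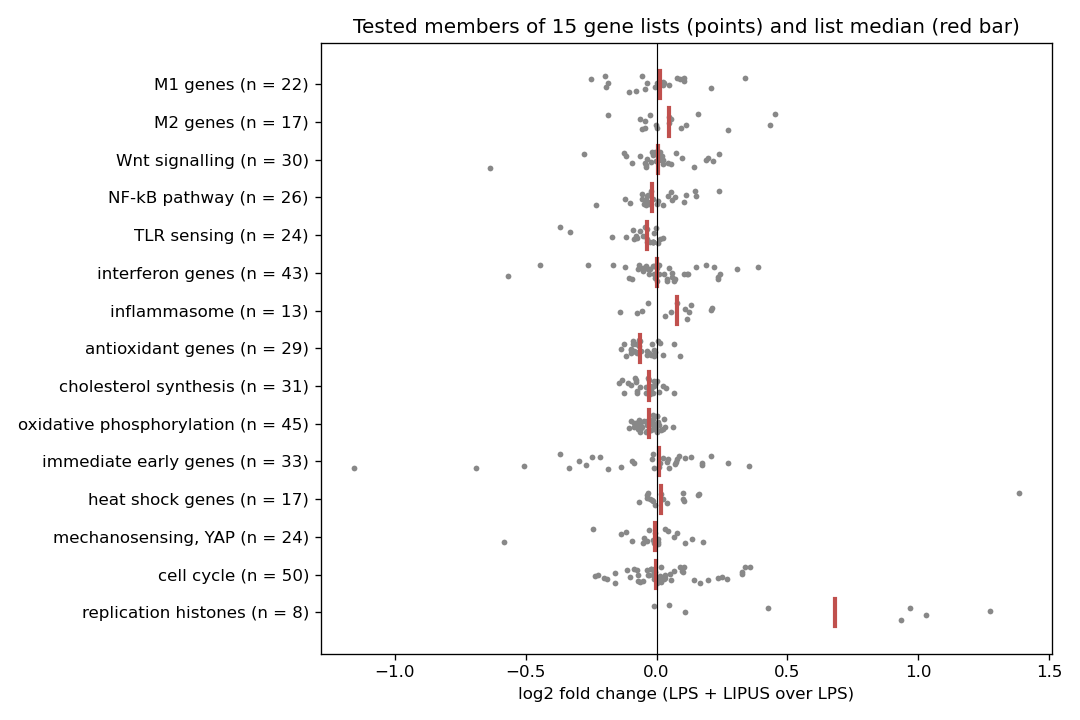
Each point is a tested gene of 1 of 15 gene lists and its x value is the log2 fold change of LPS with LIPUS over LPS; red bars are list medians and n is the number tested. The replication histones have the highest median (0.68 over 8 genes), and the M1 (0.01), M2 (0.05) and Wnt medians lie near 0.

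In the transcript table, 0 of 52257 tested transcripts passed the test (smallest adjusted p = 0.226; 2814 at an unadjusted p below 0.05). The 6 Axin1 transcripts had log2 fold changes of -0.08 to -0.03 and the 2 Ctnnb1 transcripts 0.01 to 0.02. The transcript count was 10 without LIPUS library 2 and 10 without LIPUS library 3.

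The authors' deposited table lists 351 genes as changed, 188 higher and 163 lower with LIPUS, from a median of 3 counts per library. Every gene listed in the authors' deposited table has an unadjusted p below 0.05 and an absolute log2 fold change of at least 1, and 4 of them pass a Benjamini-Hochberg adjustment over the authors' p-values for all 39089 genes: Rn7s2, Rn7s1, Ak9 and LOC115487216. Ak9, an adenylate kinase gene, had 46 counts in LPS library 1 and 0 in the other libraries; it and LOC115487216 were named after their values were seen. Wnt2b stands in the authors' deposited table with a log2 fold change of 1.07 and p = 0.0227 (1 after adjustment), and the other Wnt gene listed there, Lef1, had 7 counts, all in LPS library 1. None of the M1 or M2 genes is listed in the authors' deposited table. The filter on low counts removed 322 of the 351 genes, and of the 29 tested here 0 passed the main test and 26 had an unadjusted p below 0.05.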

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

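The removal of length and GC trends, the comparison of the histone list with cell cycle genes and with other histone genes, and the counts over other splits of genes by the authors' thresholds and of genes at 0 in 1 group were tests chosen after the results were seen.

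Among genes below the filter, Clec9a, a dendritic cell receptor gene, drew attention because it had 13 counts over the LIPUS libraries (6, 3 and 4) and 0 in LPS. Echdc2 had 12 (7, 2 and 3) and Gm52286 11 (5, 3 and 3), again with 0 in the LPS libraries. The filter kept these out of the main test, and edgeR's exact test on all genes gave adjusted p = 0.337, 0.479 and 0.628. They were picked for having 0 counts in 1 group. In all, 5 genes below the filter had 0 counts in LPS with 2 or more in every LIPUS library and 6 the reverse, 11 in both directions together. The other splits of the 6 libraries gave 2 to 8 such genes per direction and 7 to 12 in both.

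The number of genes that the authors' thresholds call was 351, and in simulated libraries with no changed gene the same rule called 226 to 279 genes. Low counts that pass an unadjusted threshold may therefore account for most of such a list, since 279 calls arose with no difference at all. Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 351 calls and the highest of the others 353, and 2 of the 10 gave at least 351. With 10 splits no share below 0.05 can arise. Between-library differences beyond the simulated spread, or a response to ultrasound in some genes, stay open for the remainder.

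The 100 genes with the smallest p were long and low in GC: 85 were higher with LIPUS, their median length was 6613.5 bases against 3496 for all tested genes, and their median GC content 41.4% against 49.8%. With each library's length and GC trend removed, the first 100 had a median length of 4838.5 bases (95% interval 3782 to 5919) and a median GC content of 45.1% (42.6% to 47.6%), and 74 were higher. The trends thus go with much of the excess in length. Both intervals still left out the medians of all tested genes. Only a smooth trend per library was removed, which can leave part of a bias, so this cannot decide whether the trends are the whole cause. The correlation of fold change with length across genes was 0.17 in the real split, and 6 of the 9 other splits gave one at least as large, up to 0.42, so single libraries may carry the trend, with LIPUS library 3 at 0.45 and LIPUS library 2 at -0.34 for the correlation of a gene's deviation with its length. A response to ultrasound in part of these genes stays open and was not tested apart from the libraries. Thoc2, Socs4, Mki67, Smc5 and Rev3l were among the 100 genes, so the same limit holds for them.

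The higher median of the replication histone genes was weighed against a larger share of cycling cells. It was assumed, and not tested, that this would raise cell cycle genes by about as much. The 50 cell cycle genes had a median log2 fold change of -0.003 and a mean of 0.03 (upper 95% limit 0.0679). The 8 histone genes had a median of 0.68 and a mean of 0.60 (95% interval 0.17 to 1.02). Both intervals treat genes as independent and do not measure the spread between libraries. On that assumption the values argue against a larger share of cycling cells as the cause of the 0.68. This does not hold for every choice. The histone median was 0.21 without LIPUS library 2 and 0.11 with the 1 CPM filter (5 genes, 95% interval of the mean -0.19 to 0.79). Of the cell cycle genes, Mki67 (0.25), Cenpe (0.27) and Cenpf (0.36) were higher, but Ube2c (-0.20) was lower and 25 of the 50 were negative. A larger share of cycling cells thus stays open for the histone genes that the 1 CPM filter leaves. Replication-dependent histone genes outside the list had a median of 0.18 with 17 of 20 higher, which leaves open whether histone messages in general differed. Reads shared between histone copies, and the effect of poly(A) selection on messages that mostly lack the tail, were not tested. The camera p was 6.04e-07 in the real split and 2.00e-08 at its smallest in another, with too few splits for a share below 0.05.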

How the results depend on the processing

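The offsets for length and GC and the exact test were added after the data were seen. The count of 0 genes held with DESeq2, limma-voom, both limma-trend fits on TPM, both other scalings, the 1 CPM filter and the offsets. The stricter thresholds on the main fit could give no other count. The count became 31 (23 higher, 8 lower) with no filter, 351 (188 and 163) by the exact test at an unadjusted p and a fold of 2, and 7 (4 and 3) by the exact test with adjustment. Of the 31, only Ak9 had been removed by the filter, so the others were genes already tested. Fosb, for example, had an unadjusted quasi-likelihood p of 1.80e-44 without the filter and 0.0205 with it. The cause was not tested. Leaving out 1 library gave 0 to 6 genes (0 to 4 higher, 0 to 2 lower) and 0 to 10 transcripts.

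Over all tested genes replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at 0.009, -0.07 and 0.01, and not every library correlated best with its own number. Such a correlation can miss a pairing limited to some genes. Fos and Fosb, for example, rose from number 1 to number 3 in both groups. With the replicate number as a block, 5 genes (1 higher, 4 lower: Gm10499, Rn7s2, Fos, Fosb and Rn7s1) and 11 transcripts passed, and none of the 5 lists recomputed (M1, M2, Wnt, antioxidant, histone) changed its side of the threshold.

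The antioxidant list (median -0.064) and the histone list (0.68) lost their calls with an estimated correlation and with fry. Without single libraries their medians were -0.074 to -0.042 and 0.21 to 0.78. The Wnt2b log2 ratio, 1.10, was 0.95 to 1.32 without single libraries. M1 medians were -0.05 to 0.07, M2 -0.02 to 0.09 and Wnt -0.01 to 0.02, none past the test. At an unadjusted p, 26 of the genes listed by the authors passed the main test instead of 0. Of 2203 alternative values for 130 named genes, 25 newly passed the threshold and 17, in 8 genes, had the opposite sign with neither value past it. The filter on low counts removed 322 of the 351 genes listed, and whether more depth would change this was not tested.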

Other observations

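The tests in this part were chosen before their results were seen, except the counts of genes over other splits. Metabolic and housekeeping lists had medians slightly below 0, and none passed a test. Members of a list can move together (estimated correlation 0.593 for oxidative phosphorylation and 0.947 for ribosomal protein genes), so the counts of signs are not of independent genes. Cholesterol synthesis genes had a negative fold change in 26 of 31 tested members (median -0.03, camera adjusted p = 0.0848), with Dhcr7 at -0.12 ± 0.07 (SE) and Acly at -0.08 ± 0.05. Nuclear genes of oxidative phosphorylation were negative in 34 of 45 (median -0.03, adjusted p = 0.0848), cytosolic ribosomal protein genes in 37 of 48 (-0.03, 0.142), hypoxia and glycolysis genes in 28 of 35 (-0.04, 0.142), lysosome and autophagy genes in 26 of 37 (-0.02, 0.463) and lipid efflux genes in 14 of 18 (-0.04, 0.243). For all 45 oxidative phosphorylation genes and all 48 ribosomal protein genes the 95% interval lay within 1.25-fold. In these lists 0 genes passed over all genes or adjusted over the list alone.

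Among growth and stress lists, the cell cycle list had 25 members on each side of 0, and Mki67 passed when adjusted over the list alone (adjusted p = 0.00792). The mitotic genes Cenpe (0.27 ± 0.10) and Cenpf (0.36 ± 0.14) were on its side and Ube2c (-0.20 ± 0.08) on the other, and camera gave an adjusted p of 0.523. The p53 and apoptosis list (median -0.01, mean 0.01, adjusted p = 0.934), the ER stress list (median -0.003, mean 0.01, adjusted p = 0.934), MAPK and PI3K feedback genes (0.01, 0.536) and TGF-beta and matrix genes (-0.004, 0.929) lay near 0. Osteoclast genes had a median of -0.01 (adjusted p = 0.536), with the fusion gene Dcstamp at -0.21 ± 0.11. Macrophage identity genes had a median of -0.03 (adjusted p = 0.842), with Ptprc at 0.15 ± 0.05, and antigen presentation genes -0.02 (0.812).

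Most markers of other cell types were below the filter on low counts; of 12 dendritic markers 4 were tested, among them Cd83 at 76.9 ± 6.98 CPM with LPS and 77.1 ± 8.17 with LIPUS (SD, n = 3 each). The 15 lymphoid markers in the table had 39 counts over all libraries. Single members passed when adjusted over their short lists alone: Col1a1 (fibroblast list, 2 tested, log2 fold change -1.34 ± 0.46, 52 against 19 counts, adjusted p = 0.0185), Csf3r (granulocyte list, 2 tested, -0.45 ± 0.17, adjusted p = 0.0336) and Epor (erythroid list, 1 tested, 0.92 ± 0.42, adjusted p = 0.0413), and none over all genes. The camera adjusted p of these lists was 0.570, 0.617 and 0.126, and that of the dendritic and epithelial lists 0.991 and 0.570. In the list of nuclear and structural RNAs Rn7s1 passed adjusted over the list alone (adjusted p = 3.66e-04), with a list median of 0.02, a mean of -0.29 and a camera adjusted p of 0.570. In all, 7 of the 32 tested lists had a member past the threshold over the list alone, Epor included. These values are not adjusted across lists, so some would arise with no difference.

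The 7SL copies differed more between LPS libraries than between groups: per total count, Rn7s2 was 23.3 times and Rn7s1 8.40 times as abundant in LPS library 2 as in LPS library 1. Other RNAs without a poly(A) tail did not follow, as the larger of the ratios for Rn7sk and for summed small nuclear RNAs was 1.06.

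For the other counts, the real split of the 6 libraries gave 0 genes and 0 transcripts past an adjusted p of 0.05, and the highest of the other splits 20 genes and 16 transcripts. Both came from LPS library 1 with LIPUS libraries 1 and 2 against the rest, which points to a structure of the samples that the groups do not describe. Of those 20 genes 10 belong to the immediate early list. Fos, Fosb, Egr1, Jun, Junb, Ier2, Dusp1, Zfp36 and Arc were lower in LPS library 1 and LIPUS libraries 1 and 2, and Gadd45b was higher there. The 20 also held genes named above for the groups: Rn7s2, Rn7s1 and Socs3, lower there on average, and Hspa1b, higher there. Their log2 fold changes, the rest over those libraries, were 3.68, 2.21, 0.33 and -1.70. Their differences thus do not follow the groups alone. Egr1, for example, had 598 counts in LPS library 1 and 530 and 619 in LIPUS libraries 1 and 2, but 1131, 1397 and 925 in the other libraries. Genes of this paragraph were picked for it after their values were seen. For the antioxidant list the camera p was 4.62e-04 in the real split and 1.17e-04 at its smallest in another. There were 10 splits, too few for a share below 0.05.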
